A study of Mus musculus with 3 samples.

How the data were processed

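Single cells of 3 libraries were captured with the DECODER 3′ kit in the Well-Paired-Seq format, per the labels' protocols, which also name a CUT&Tag kit whose role in these RNA libraries they do not state. The submitters' processing notes name Trim Galore and the mouse build mm10; the aligner, the counting tool and the annotation are not given in the sources used here. The deposited table is called counts but holds natural log values: each is the natural log of 1 plus the cell's count scaled to 10000 counts per cell. After the log was removed every one of the 38397 cells summed to 10000, and 100% of the 66511263 values above 0 came out as whole counts within a tolerance of 0.01, so whole counts were worked back and used for sums. The design fixed beforehand had assumed a count table. Cells were assigned to libraries by the start of their names, which hold the group name, and 0 columns were left unassigned. The numbers at the end of the names, 1 for EKD_Glc_IEVs, 2 for Glc_IEVs and 3 for IEVs, run opposite to the library numbers in the labels, which give IEVs as 1. Were the end numbers the right key, the values of IEVs and EKD_Glc_IEVs would be exchanged. Of the 32285 rows, 26026 had a count in some cell. All cells had from 1000 to 19966 counts, so cells had been selected before deposit by a step that the sources used here do not give.

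The rows have no names, and no gene was inferred from their order. The planned marker genes, gene lists, ezrin levels, mitochondrial limit and gene name exclusions were therefore not used here. The naming rule, fixed before the data were examined, orders rows of at least 50 CPM in the higher library by the bound of the ratio interval nearest to 1. That rule would have named more rows over all cells and further rows within clusters. In a departure from it, only the first 2 rows each way over all cells are named per comparison. Cells with at least 500 counts and 200 rows were kept, which left out 4 cells of IEVs.

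Clustering took 2000 variable rows, 30 principal components, 15 nearest neighbours and Leiden resolution 1 on the 3 libraries together, without integration. The nearest-neighbour graph was replaced by an exact shared-neighbour graph after a first clustering had been seen, because the first changed with the number of processor threads. Scrublet called 0 doublets in all 3 libraries and is taken as not having worked, so doublets stayed in. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, scanpy 1.11.5, leidenalg 0.10.2 and python-igraph 0.11.9 were used.

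Counts were summed per library, or per library and cluster, and divided by the total (CPM). CPM has exact Poisson intervals, ratios have exact conditional intervals and shares have exact Clopper-Pearson intervals, all at 95% and for counting error only. SDs of log2 ratios use a pseudocount of 0.5 counts, and the position measure uses 0.5 CPM. Overlap of cluster shares is the sum over clusters of the smaller of the shares of both libraries. In simulated counts with 50 rows changed at each of 4 fold sizes, the interval held the true ratio for 95.1% of 3582 rows for Glc_IEVs against IEVs and 95.7% of 3647 rows for EKD_Glc_IEVs against Glc_IEVs, and a simulated fold of 2 was recovered at a median of 2.01 and 2.00. These were Poisson counts drawn from library totals, for which the interval is exact, so this checks the calculation only. Clumping of counts within cells was not simulated. No p-value was computed. The comparisons share libraries, and so share their chance values.

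Alternatives fixed before the data were examined were no cell filter, a filter of 1000 counts and 500 rows, Leiden resolutions 0.5 and 2, trimmed-mean and median-of-ratios scaling, the mean of per-cell CPM, and the same cluster weights in every library, each the mean share of the cluster over the libraries, over the 9 clusters with at least 100 cells in every library. Added after seeing the data were thinning to 1000 counts, cells of 1500 to 3000 counts with and without thinning, thinning with the same cluster weights, 9 other seeds, removal of the 5% deepest cells of each library, removal of clusters 17 and 18, and differences of mean natural log values.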

Results

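The data were single-cell RNA-seq libraries of mouse liver cancer, labelled with Hepa 1-6, a mouse hepatoma cell line, after treatment with vesicles. The series describes the treatment as glucose-free microvesicles, and the labels do not spell out the abbreviation IEVs. There were 3 groups with 1 library each: IEVs (genotype label wild type), Glc_IEVs (wild type) and EKD_Glc_IEVs (genotype label Ezrin knockdown; ezrin links the plasma membrane to the actin cytoskeleton). The deposited table held 9075 cells of IEVs, 17135 of Glc_IEVs and 12187 of EKD_Glc_IEVs. Counts worked back from it summed to 23456180 in IEVs, 88145254 in Glc_IEVs and 48311863 in EKD_Glc_IEVs. The rows of the table carry no gene names, so levels are given for row numbers, clusters are given by number, and the level of the ezrin transcript, marker genes and gene lists were not analysed here. With 1 library per group no difference has a replicate check, no test was possible between groups, and all intervals are 95% intervals that cover counting error only.

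The cells of the Glc_IEVs library were deeper than those of the IEVs library. The median cell held 1878 counts in IEVs, 3497 in Glc_IEVs and 2095 in EKD_Glc_IEVs, and the median number of rows detected per cell was 1070, 1729 and 1253, respectively. Cells with at least 5000 counts made up 8.75% of IEVs (exact binomial interval 8.18% to 9.35%), 38.8% of Glc_IEVs (38.0% to 39.5%) and 23.5% of EKD_Glc_IEVs (22.8% to 24.3%). With every cell thinned to 500 counts, the median number of rows detected was 389 in IEVs, 400 in Glc_IEVs and 406 in EKD_Glc_IEVs, so most of the difference in rows detected went with depth.

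The comparison of Glc_IEVs with IEVs asks how the vesicle treatment labelled Glc differs from the one without that label. The cells of these libraries fell largely into different clusters. Clusters 1 and 2 held 28.2% (27.6% to 28.9%) and 27.4% (26.7% to 28.1%) of the Glc_IEVs cells but 0.661% (0.505% to 0.851%) and 0.375% (0.260% to 0.523%) of the IEVs cells. Cluster 7 held 27.5% (26.6% to 28.4%) of the IEVs cells and 2 of the 17135 Glc_IEVs cells. Cluster 13 held 9.28% (8.69% to 9.90%) and cluster 18 held 4.33% (3.92% to 4.77%) of the IEVs cells. Each held 0 of the 17135 Glc_IEVs cells, for which the exact interval allows a share of up to 0.0215%. The shares of the 21 clusters overlapped by 18.9% between Glc_IEVs and IEVs, whereas random equal parts of 1 library overlapped by 97.9% on average. A cluster mostly of 1 library may be that library and not a cell type, and the depth gap stands beside every share. On average 85.7% of the nearest neighbours of a Glc_IEVs cell and 78.2% of those of an IEVs cell came from the same library, against 44.6% and 23.6% if cells had mixed freely.

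**Figure D1:**
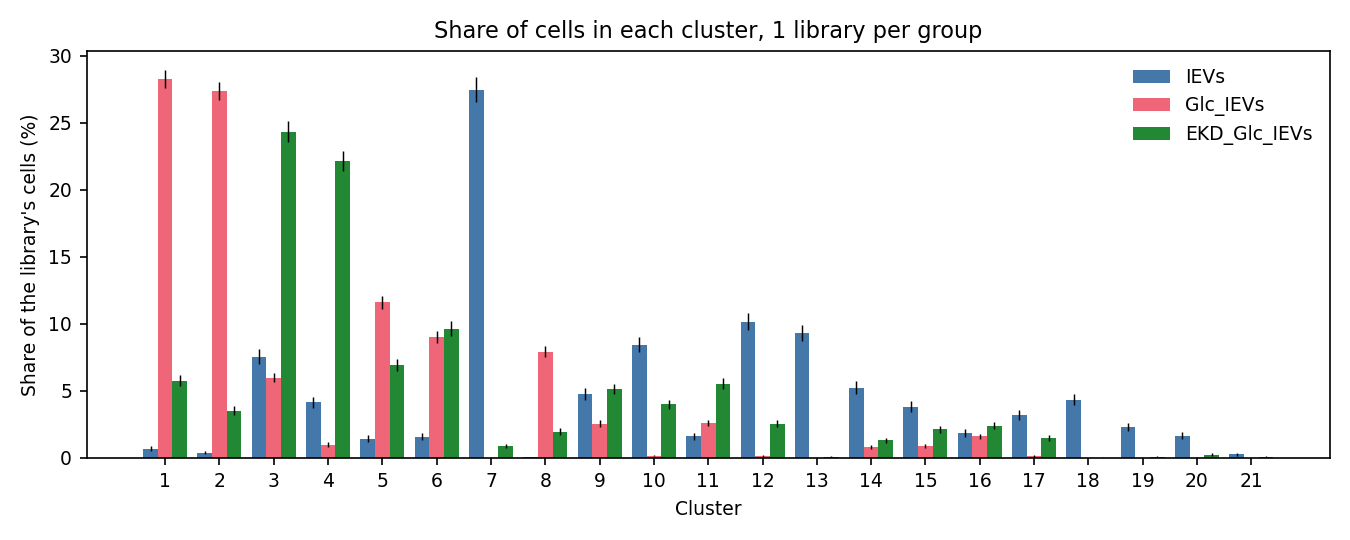
Share of each library's cells (%, y axis) in each of the 21 clusters (x axis) for IEVs, Glc_IEVs and EKD_Glc_IEVs, with 1 library per group; bars are shares and error bars exact 95% binomial intervals. Clusters 1 and 2 hold 28.2% and 27.4% of Glc_IEVs, cluster 7 holds 27.5% of IEVs, and clusters 3 and 4 hold 24.3% and 22.1% of EKD_Glc_IEVs.

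Levels over all cells also differed between Glc_IEVs and IEVs. Among the 4651 rows of at least 50 CPM (counts scaled to a library total of 1000000) in a library, the log2 ratio of CPM had an SD of 1.75, against 0.11 to 0.15 between random equal parts of 1 library. With the same cluster weights in every library the SD was 1.00. Here and below, these weights cover only the 9 clusters with at least 100 cells in every library. Those clusters hold 36.0% of the Glc_IEVs and 31.9% of the IEVs cells, so cells were dropped as well as reweighted. A larger part of EKD_Glc_IEVs was kept, as they include clusters 3 and 4, with 24.3% and 22.1% of its cells. Clusters 3 and 4 carry 25.7% and 18.5% of the weight, and cluster 4 rests on 169 Glc_IEVs cells. Values of EKD_Glc_IEVs with these weights thus set a larger part of it against smaller parts of the other libraries. row11914 was at 103 CPM (101 to 105) in Glc_IEVs and 2.69 CPM (2.06 to 3.44) in IEVs, a ratio of 38.3 (29.9 to 49.9). row22105 was at 65.7 CPM (64.0 to 67.4) in Glc_IEVs and 2.004 CPM (1.47 to 2.66) in IEVs, a ratio of 32.8 (24.6 to 44.7). Cluster 8 gave 67.3% of the Glc_IEVs counts of row11914, and cluster 1 gave 57.1% of those of row22105. On the other side, row4306 was at 717 CPM (706 to 728) in IEVs and had 1 count in Glc_IEVs, and row30326 was at 914 CPM (902 to 926) in IEVs and had 3 counts in Glc_IEVs. With the same cluster weights in every library, the log2 ratio of row11914 was 4.57 against 5.25 over all cells, and that of row22105 was 3.49 against 5.02. For row4306 it was -12.21 against -15.36 and for row30326 -11.00 against -14.49, values that rest on at most 1 and 3 counts in Glc_IEVs and on the pseudocount. Cluster 18 gave 71.3% of the IEVs counts of row4306 and 74.6% of those of row30326.

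These 4 rows differed in the same direction in each of the 9 clusters with at least 100 cells in both libraries. This is not independent evidence cluster by cluster: the rows were chosen for their ratios over all cells, low counts of rows of cluster 18 were present throughout the IEVs library, and free RNA was not measured in Glc_IEVs. There were 24 rows at 50 CPM or more in IEVs and at 1 CPM or less in both other libraries, and no row met such limits with Glc_IEVs or EKD_Glc_IEVs as the high library. Of them, 22 were highest in cluster 18, where they took 21.6% of the counts. Outside cluster 18, 87.6% of the IEVs cells held at least 1 count of these 22 rows, with a median of 3 counts per cell. Within clusters 3, 9 and 4, the clusters with the most cells in their smaller library, the SD of the log2 ratio was 0.82, 1.11 and 0.87. Random equal parts gave up to 0.32 in cluster 3, 0.37 in cluster 9 and 0.68 in cluster 4.

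**Figure D2:**
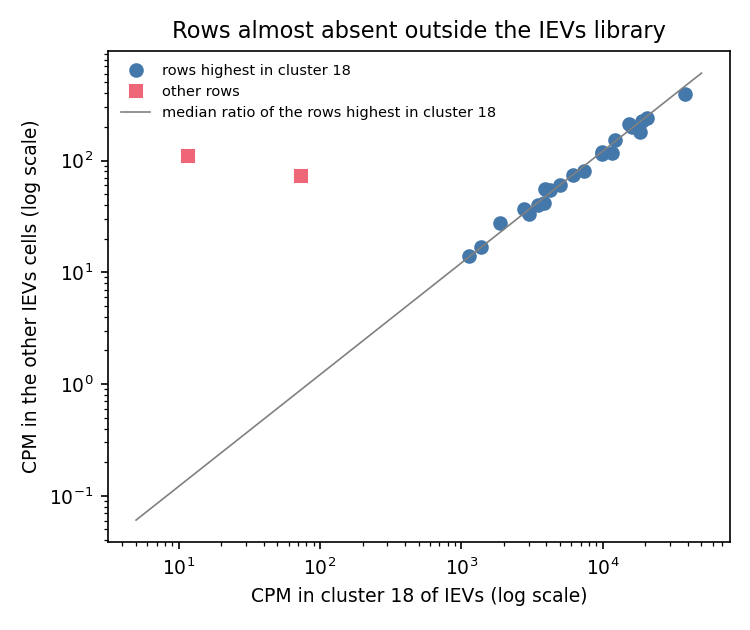
CPM in cluster 18 of the IEVs library (x axis, log scale) and in its other cells (y axis, log scale); each point is 1 of the 24 rows at 50 CPM or more in IEVs and at 1 CPM or less in both other libraries. The 22 rows highest in cluster 18 lie along the line of their median ratio, 0.0121, and the other 2 rows lie far above it.

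The comparison of EKD_Glc_IEVs with Glc_IEVs asks how the library with the Ezrin knockdown genotype differs from the wild type under the Glc label. Clusters 3 and 4 held 24.3% (23.6% to 25.1%) and 22.1% (21.4% to 22.9%) of the EKD_Glc_IEVs cells, against 5.99% (5.64% to 6.35%) and 0.986% (0.844% to 1.15%) of the Glc_IEVs cells. Clusters 1 and 2 held 5.76% (5.35% to 6.19%) and 3.504% (3.18% to 3.85%) of EKD_Glc_IEVs, well below their shares of Glc_IEVs. Cluster 6 held similar shares, 9.64% (9.12% to 10.2%) of EKD_Glc_IEVs and 9.02% (8.59% to 9.46%) of Glc_IEVs. Cluster shares overlapped by 43.0% between these libraries. Because the labelled knockdown could not be read from the ezrin transcript here, the genotype is that of the label alone.

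Over all cells the log2 CPM ratio of EKD_Glc_IEVs to Glc_IEVs had an SD of 0.81, and of 0.54 with the same cluster weights in every library. row21832 was at 847 CPM (839 to 855) in EKD_Glc_IEVs and 24.7 CPM (23.6 to 25.7) in Glc_IEVs, a ratio of 34.3 (32.9 to 35.8). row21838 was at 779 CPM (771 to 787) and 27.2 CPM (26.2 to 28.4), a ratio of 28.6 (27.4 to 29.8). Both were higher still in IEVs, at 3799 and 1549 CPM. Cluster 17, with 1.47% of the EKD_Glc_IEVs cells and 0.123% of the Glc_IEVs cells, gave 79.7% of the EKD_Glc_IEVs counts of row21832 and 76.2% of those of row21838. row28702 was at 17.7 CPM (16.5 to 18.9) in EKD_Glc_IEVs and 158 CPM (155 to 161) in Glc_IEVs, a ratio of 0.112 (0.104 to 0.120). row4699 was at 32.7 CPM (31.1 to 34.3) and 219 CPM (216 to 222), a ratio of 0.149 (0.142 to 0.157). Cluster 1 gave 58.3% of the Glc_IEVs counts of row28702 and 56.8% of those of row4699. The direction of these 4 rows was the same in each of the 12 clusters with at least 100 cells in both libraries, which is not independent evidence cluster by cluster for the same reasons of choice and unmeasured free RNA. Whether the counts of row21832 and row21838 outside cluster 17, seen in 24.4% and 28.4% of all EKD_Glc_IEVs cells with cluster 17 included, came from its cells was not tested. With the same cluster weights in every library, the log2 ratio of row21838 was 2.55 against 4.84 over all cells, and that of row21832 was 4.26 against 5.10. Without clusters 17 and 18 they were 4.14 and 6.37, so that of row21832 moved both ways. Within clusters 6, 3 and 5 the SD of the log2 ratio was 0.54, 0.45 and 0.33, against at most 0.19, 0.22 and 0.11 between random equal parts.

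Total-count scaling set these levels. Trimmed-mean scaling moved the log2 ratios of Glc_IEVs to IEVs by 0.44 and median-of-ratios scaling by 0.45, and those of EKD_Glc_IEVs to Glc_IEVs by -0.34 and -0.39.

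The EKD_Glc_IEVs library was also set against IEVs. Their cluster shares overlapped by 36.63%, but by 64.5% at Leiden resolution 0.5, 61.1% after thinning to 1000 counts and 56.6% without the deepest cells. The 9 other seeds gave 36.66% to 53.1%, each above the main value. This overlap thus has no stable order against the 43.0% of EKD_Glc_IEVs and Glc_IEVs. The log2 CPM ratio had an SD of 1.22, and of 0.76 with the same cluster weights in every library. In every setting run, this SD was above that of EKD_Glc_IEVs to Glc_IEVs. The latter was 0.81 over all cells and 0.54 with the same weights. By this measure EKD_Glc_IEVs lay nearer to Glc_IEVs, an order without a replicate check. For rows that differed at least 2-fold between Glc_IEVs and IEVs, chosen in 1 random part of the cells and measured in the other, EKD_Glc_IEVs lay at a position of 0.630 on a scale from 0 at IEVs to 1 at Glc_IEVs. Simulated libraries that deviate independently and alike gave 0.544 on average (0.510 to 0.581). They had the same spread in every library, whereas the observed SDs were 1.75, 0.81 and 1.22 for the 3 pairs. This range is therefore not a bound for the observed position, and it was not computed for higher and lower rows apart. The position of EKD_Glc_IEVs was 0.439 in cells of 1500 to 3000 counts thinned to 1000 counts. With the same cluster weights in every library it was 0.464, over 376 rows against 1630 over all cells. It was 0.488 with the mean of per-cell CPM and 0.582 without the deepest cells, so no order of the libraries is read from this pooled value. Over all cells the position was 0.843 for the 708 rows higher in Glc_IEVs and 0.439 for the 922 lower rows. In every setting run, the higher rows lay above 0.5 (0.565 to 0.846) and the lower rows below it (0.265 to 0.466). The position was not computed under trimmed-mean or median-of-ratios scaling, which act on higher and lower rows in opposite directions. These scalings moved the log2 ratios of Glc_IEVs to IEVs by 0.44 and 0.45, and those of EKD_Glc_IEVs to IEVs by 0.10 and 0.06. For the lower rows over all cells, the median log2 ratios of IEVs were 2.23 to Glc_IEVs and 0.98 to EKD_Glc_IEVs. Both would shrink under these scalings, so the lower rows may not stay below 0.5 there.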

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

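Thinning to 1000 counts, alone or with the same cluster weights, the depth window with and without thinning, other seeds and the removal of deep cells or of clusters 17 and 18 were chosen after seeing the data. The direction of each of the 8 named rows held in all 96 alternative log2 ratios, of which 28 moved by more than 0.5, and in all 8 differences of mean natural log values; the rows had been chosen for extreme ratios, and the scalings among these settings shift every row alike by too little to turn one. The overlap of Glc_IEVs with IEVs, 18.92%, was 27.6% at Leiden resolution 0.5, 17.7% at 2, 16.2% with no filter and 16.03% with the stricter filter. It was 17.03% without the deepest cells and 24.8% after thinning. The 9 other seeds gave 15.5% to 18.86%, each below the main value. This overlap stayed the lowest of the 3 overlaps in each setting. The overlap of EKD_Glc_IEVs with Glc_IEVs, 43.0%, was 47.2%, 40.9%, 40.9%, 46.0% and 45.4% at resolutions 0.5 and 2, with no filter, with the stricter filter and after thinning, and 39.9% to 46.9% with other seeds. That of EKD_Glc_IEVs with IEVs, 36.6%, was 64.5% at resolution 0.5, 45.0% with no filter, 46.3% with the stricter filter, 56.6% without the deepest cells, 61.1% after thinning and up to 53.1% with other seeds. Which of Glc_IEVs and IEVs lies nearer to EKD_Glc_IEVs by overlap thus changes with the setting, even with no filter, which adds 4 cells; the cause was not tested. With the same cluster weights in every library the SDs of log2 ratios were 1.00 for Glc_IEVs over IEVs, 0.54 for EKD_Glc_IEVs over Glc_IEVs and 0.76 for EKD_Glc_IEVs over IEVs, from 1.75, 0.81 and 1.22; with thinning added they were 0.94, 0.50 and 0.75. In cells of 1500 to 3000 counts the first was 1.44 and the last 1.02 with thinning, and 1.48 and 1.03 without. The position, 0.630, was 0.488 with the mean of per-cell CPM, 0.488 with every cell thinned, 0.464 with the same cluster weights, 0.488 with those weights and thinning, and 0.439 with and 0.441 without thinning in cells of 1500 to 3000 counts, all on the other side of 0.5. It stayed on its side at 0.582 without the deepest cells, 0.614 without clusters 17 and 18, and 0.630 with either other filter. By bounds around 0.5 written beforehand, the depth window met that for counts per cell and same cluster weights that for cluster makeup. The 0.510 to 0.581 of simulated libraries was not computed for these settings. The window also changes which cells are compared, and its move came without thinning. Mean per-cell CPM, unthinned, gave the 0.488 of thinned cells, so counts per cell were not shown as the cause. The median log2 ratio of EKD_Glc_IEVs over Glc_IEVs, 0.11, was -0.23 with trimmed-mean and -0.28 with median-of-ratios scaling. Removal of Scrublet calls changed nothing because there were none, and clustering each library on its own was not run, since its plan named clusters by marker genes. No paired analysis was possible because each group has 1 library.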

Other observations

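The tests on the 24 rows almost confined to IEVs were chosen after the result was seen, and their split into 22 and 2 rows after the 2 had been seen to differ, as were the intervals on the depth ratios within clusters; thinning before clustering was added after the table had been seen, with its bounds written before its result.

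The 24 rows stood at 9718 CPM in IEVs, 1.89 CPM in Glc_IEVs and 3.81 CPM in EKD_Glc_IEVs. For the 22 rows highest in cluster 18, free RNA from the cells of that cluster may account for the counts in other IEVs cells: their CPM outside cluster 18 stood at a median of 0.0121 of that inside it, and the 90th percentile of this ratio over rows was 1.30 times the 10th. This is the spread of a part chosen from the same data: over all 24 rows the highest ratio was 965 times the lowest. Doublets with such cells as the whole source are argued against, since 87.6% of the cells outside the cluster held a count. The match is not exact, as the chi-square per degree of freedom against the profile of cluster 18 ran from 0.806 to 10.4 over 16 clusters, and the level was uneven: cluster 13 had a median of 10 counts per cell against at most 4 elsewhere, and clusters 13 and 16 had means of 17.7 and 15.6 against at most 7.50, so another source in these clusters stays open. The other 2 rows, set apart because another cluster had their highest CPM, stood outside cluster 18 at 0.981 and 9.38 of their CPM inside it, up to 685 times that 90th percentile; these levels, and no independent test, argue against cluster 18 as their source. Why cluster 18 was seen in IEVs alone cannot be told apart between treatment, tissue sampled and library with 1 library per group.

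Cluster shares differed between the libraries. Thinning every cell to 1000 counts moved the overlap of Glc_IEVs with IEVs 0.0746 of the way to that of random equal parts of 1 library. This argues against counts per cell as the whole cause for this pair. The same thinning took the overlap of EKD_Glc_IEVs with Glc_IEVs from 43.0% to 45.4%. That of EKD_Glc_IEVs with IEVs went from 36.6% to 61.1%, though other seeds alone gave up to 53.1%. No bound was written for these pairs, so counts per cell stay open for EKD_Glc_IEVs with IEVs. Treatment and library preparation cannot be told apart with 1 library per group.

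The median counts per cell were 1.86 times higher in Glc_IEVs than in IEVs. Deeper sequencing of every cell alike stays open: the 9 clusters with at least 100 cells in both libraries gave ratios from 0.605 to 3.99, with intervals from resampled cells wholly below 1 in 2 and wholly above 1 in 3, but their 90th over 10th percentile of 2.02 (1.79 to 2.39) did not pass its bound of 2 by more than its error, and clusters made at full depth, with 1 library per group, do not part depth from cell type. Cluster makeup stays open too: the share of the log ratio left within clusters was 0.395 with clusters weighted by their cells and 0.165 with each cluster counted alike, on different sides of the bound, and these clusters hold 36.0% of the Glc_IEVs and 31.9% of the IEVs cells.

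Cell barcodes shared between libraries numbered 227 (198 to 259) for Glc_IEVs and IEVs, where chance gives 204. They numbered 265 (234 to 299) for EKD_Glc_IEVs and Glc_IEVs, where chance gives 271. For EKD_Glc_IEVs and IEVs they numbered 172 (147 to 200), where chance gives 151. Each Poisson interval holds its chance value.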
